A study of Mus musculus with 8 samples.

How the data were processed

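RNA sequencing libraries were made from the cortex of APP/PS1 mice on a C57BL/6 background, a transgenic line that forms amyloid plaques. Per the labels, 4 libraries came from mice given bexarotene, an agonist of retinoid X receptors, and 4 from mice given glycerol at 0.2 mg/kg, called vehicle here. The dose and duration of bexarotene, the age and the sex of the animals are not given in the sources used here. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether a library holds 1 animal or several, so p-values measure only the spread between these libraries.

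Per the labels' protocols, RNA was extracted with a Qiagen RNeasy kit and libraries were prepared with a stranded TruSeq mRNA kit. The deposited values are raw read counts per RefSeq transcript, as the whole numbers and the unequal column totals show. The submitters' processing notes name the mouse genome build mm9, and the submitters' notes and design text name edgeR. The aligner, the counting program, its strand setting and the annotation release are not given in the sources used here. Because the strand setting is unknown, reads of overlapping genes on opposite strands cannot be told apart.

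The deposited count table had 28644 rows for 22869 gene symbols, and 3705 symbols had more than 1 row. Of the symbols with more than 1 row, 18.1% held identical counts in all their rows. The rule by which reads were assigned to isoforms is not given, so totals over all rows are sums of table entries and not numbers of reads. They ranged from 42413825 to 76542067 per library, and from 29089954 to 52479182 when 1 row per symbol was kept. Levels below are in CPM, counts scaled to a common library size, relative to the total over the tested rows times the TMM factor. The highest Pearson correlation of log2 CPM between libraries was 0.993, between bexarotene replicates 1 and 3, followed by 0.985 between bexarotene replicates 2 and 4. Vehicle replicates 1 and 3 correlated at 0.972, and vehicle replicates 2 and 4 at 0.957. In the deposited table, 0 columns of values were left out.

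The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on all 8 libraries with TMM factors, the default low-count filter, robust dispersion estimates and the group as the only term. Benjamini-Hochberg adjustment was over the 21285 rows that passed the filter, which stand for 16069 genes. Each gene was represented by its row with the highest mean count. An adjusted p below 0.05 was called. Log2 fold changes are bexarotene minus vehicle, with the standard error derived from the F statistic. For single genes, an exact two-sided permutation test of the 8 log2 CPM values (prior count 2) was run beside it; the smallest p it can give with 4 against 4 is 0.0286.

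Before the data were examined, 21 gene lists and 18 lists of cell type, tissue and control markers were fixed, with 780 members in all, of which 1 was not matched to a symbol. They were tested with limma's camera (limma 3.58.1) at the preset correlation of 0.01 between genes, adjusted over the 39 lists. Camera compares a list with all other genes. The same lists were tested with a correlation estimated per list, and with fry, whose directional p asks whether the members move, on balance, one way. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. Several lists share members, so their results are not independent.

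The genes named were chosen by a rule fixed at the same time: Trem2, Tyrobp, Apoe, Abca1, App and Prnp, with 1 further gene that is not reported here, nor is the control list that holds it; the 10 largest changes per direction among genes past the threshold with a mean of at least 1 CPM and no overlap between groups; and, of each list, up to 4 members past the threshold or else the 1 or 2 with the smallest p. The rule took 55 genes, 1 of them by size of change. Any other gene named was chosen after its values were seen.

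The titles number the replicates 1 to 4 in both groups. The deviations of same-numbered libraries from their group means correlated across genes at 0.43, 0.28, 0.14 and 0.16 for replicates 1 to 4. All exceed 0.1, the level fixed for treating the numbers as pairs, so a fit with the replicate number as a block is given wherever it changed a call. The pairing comes from the titles and this check alone, and several libraries go against it. Bexarotene replicate 3 and vehicle replicate 1 correlated at 0.44, above the 0.14 and 0.43 that each had with its own number. Bexarotene replicate 4 correlated with vehicle replicate 2 at 0.23, and vehicle replicate 4 with bexarotene replicate 2 at 0.20. Both had 0.16 with their own number. Bexarotene replicate 1 and vehicle replicate 3 correlated at 0.05. Replicates 1 and 3 lay apart from replicates 2 and 4 on the first principal component. The check therefore cannot tell pairs from these clusters.

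Alternatives fixed in advance were RLE, upper quartile and no composition factors; DESeq2 1.42.0; edgeR's exact test; limma-voom with sample quality weights; no filter and a filter of 1 CPM in 4 libraries; the replicate block; each library left out in turn; counts summed per symbol; an adjusted p below 0.1; a test against a fold of 1.2; the estimated correlation; and fry. Added after the data were seen were 1 row per gene fitted alone, an offset that removes the trend with transcript length and GC content per library, this offset with the replicate block, and covariates for the Y-linked share, the striatum list and the first principal component's clusters. Transcript lengths and GC contents came from GENCODE mouse release 21, matched by RefSeq identifier for 97.0% of rows. That annotation is on another build than the counts, so no coordinates are given.

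The procedure was tested on simulated counts for 15832 genes with the means, dispersions and library sizes of the real libraries. Of the genes changed 1.5-fold, 2-fold and 4-fold, 26.9%, 61.2% and 92.4% were recovered, and 4 of 128 calls were false. The microglia list, shifted there by 0.4 on the log2 scale, was recovered by camera with an adjusted p of 9.9e-15, and 1 other list was called. The simulated genes varied independently of each other, whereas the estimated correlation between members of the real microglia list was 0.61. The simulation therefore cannot show how camera at the preset correlation of 0.01 behaves on correlated lists. This test was for the comparison of bexarotene with vehicle. Figures were drawn with matplotlib 3.10.9. PCR duplicates cannot be recognised in a count table without molecular identifiers, so counting precision is an upper limit.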

Results

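The cortex of APP/PS1 mice was profiled by RNA sequencing in 4 libraries from bexarotene-treated and 4 from vehicle-treated animals, to ask how the transcriptome and Trem2 in particular differ under treatment. Bexarotene activates retinoid X receptors, which pair with liver X, peroxisome proliferator-activated and retinoic acid receptors. Total counts over all rows of the table were 60106192, 75094528, 66824198 and 76542067 in bexarotene replicates 1 to 4, and 42413825, 58444608, 56510129 and 60955403 in vehicle replicates 1 to 4. Between 16656 and 18207 genes had a count in a library, and each of the 4 bexarotene libraries (17664 or more) had more than any vehicle library (17204 or fewer).

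The libraries fell into 2 clusters on the first principal component of log2 CPM (36.5% of the variance), and these were not the treatment groups. Replicates 1 and 3 of both groups lay on one side and replicates 2 and 4 of both groups on the other. Xist, the RNA that silences the inactive X chromosome in females, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty divided the vehicle libraries in the same way. Vehicle replicates 1 and 3 had 248 and 307 CPM of Xist and at most 0.282 CPM of the summed Y-linked genes. Vehicle replicates 2 and 4 had 134 and 141 CPM of Y-linked genes and at most 0.861 CPM of Xist. All 4 bexarotene libraries had both: Xist was at 180, 84.7, 116 and 218 CPM in replicates 1 to 4, and the Y-linked sum at 17.1, 88.5, 55.8 and 9.81 CPM. Uty alone had a log2 fold change of -0.88 ± 1.51 (SE), and its sign depended on the fit.

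**Figure D1:**
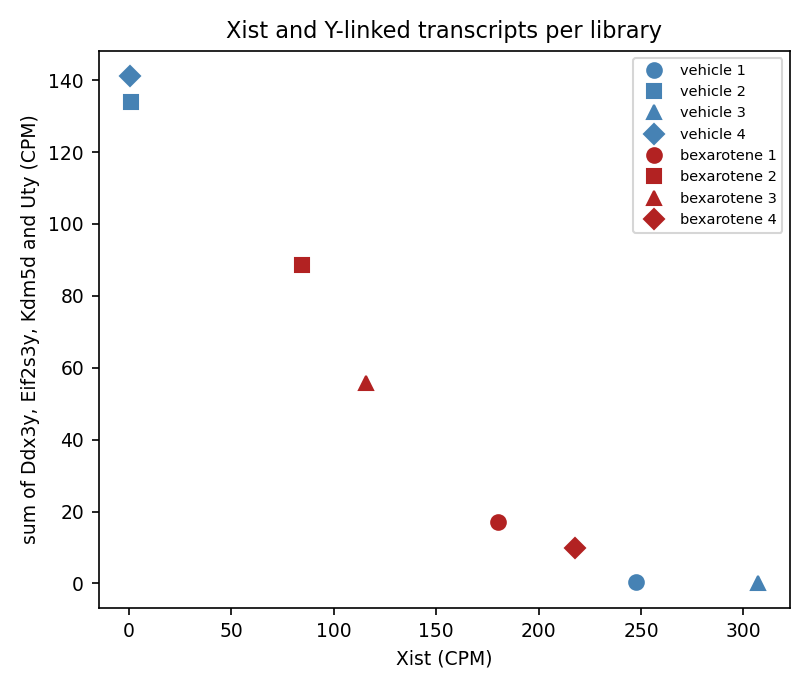
Xist (horizontal axis, CPM) against the summed Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty (vertical axis, CPM), 1 point per library. The vehicle libraries lie near 1 axis each, while the 4 bexarotene libraries have between 9.81 and 88.5 CPM of Y-linked transcripts and between 84.7 and 218 CPM of Xist.

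Rplp2, which encodes a protein of the ribosomal stalk, was the 1 gene that rose past the threshold under bexarotene. It averaged 20.5 ± 1.87 CPM under bexarotene and 6.66 ± 0.927 CPM under vehicle (SD, n = 4), 3.07-fold higher. Its log2 fold change was 1.62 ± 0.13 (SE), with an adjusted p of 0.00307 in edgeR's quasi-likelihood test, and all 4 bexarotene libraries lay above all 4 vehicle libraries. Within replicates 1 and 3 the log2 difference was 1.69, and within replicates 2 and 4 it was 1.55. Ribosomal protein genes have many processed pseudogenes, and reads shared with such copies can be split or dropped in counting. Next in rank were AA465934, an RNA of unknown function (log2 fold change 2.45 ± 0.31), and Ndufa3, a subunit of respiratory complex I (0.78 ± 0.10), both at an adjusted p of 0.0975. AA465934 was chosen after its values were seen.

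No gene fell past the threshold in edgeR's quasi-likelihood test. Of the 16069 genes tested, 784 were higher and 625 lower at an unadjusted p under 0.05. DESeq2 called 78 genes higher and 26 lower, edgeR's exact test called 34 higher and 3 lower, and 32 genes were called by both with the same direction. These calls included Ndufa3, Ndufs6, C1qb, C1qc, Fcgr1, Apoe, Bst2 and Ttr, all higher. Ndufa3 had an adjusted p of 6.86e-08 in DESeq2 and 2.78e-06 in the exact test. The groups did not overlap in 927 genes, 5.8% of those tested, and 580 of these were higher and 347 lower under bexarotene. The average share expected by chance is 2.86%. Genes vary together, and the spread of this share over other groupings was not computed, so the excess was not tested. Without bexarotene replicate 2, the quasi-likelihood test called 2 genes.

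Trem2, a receptor of microglia for lipids and apolipoproteins, averaged 37.7 ± 8.66 CPM under bexarotene and 25.8 ± 7.36 CPM under vehicle (SD, n = 4). The fitted ratio was 1.46, a log2 fold change of 0.55 ± 0.21 (SE). This difference did not pass the test: the unadjusted p was 0.0285 and the adjusted p 0.547 in edgeR's quasi-likelihood test, and an exact two-sided permutation test gave p = 0.0857. Vehicle replicate 3, at 36.6 CPM, exceeded bexarotene replicates 2 (32.1 CPM) and 3 (30.4 CPM), while the other 3 vehicle libraries had 20.5 to 23.8 CPM. Tyrobp, the signalling adaptor of Trem2, was at 36.6 ± 7.53 against 24.8 ± 7.43 CPM (SD, n = 4). Its log2 fold change was 0.56 ± 0.21, with an adjusted p of 0.527, and vehicle replicate 3 was again the highest vehicle library at 35.9 CPM. Within replicates 1 and 3 the log2 difference was 0.33 for Trem2 and 0.23 for Tyrobp. Within replicates 2 and 4 it was 0.79 and 0.93. Without vehicle replicate 3 the log2 fold change of Trem2 was 0.77. With the length and GC offset it was 0.37 for Trem2 and 0.29 for Tyrobp.

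**Figure D2:**
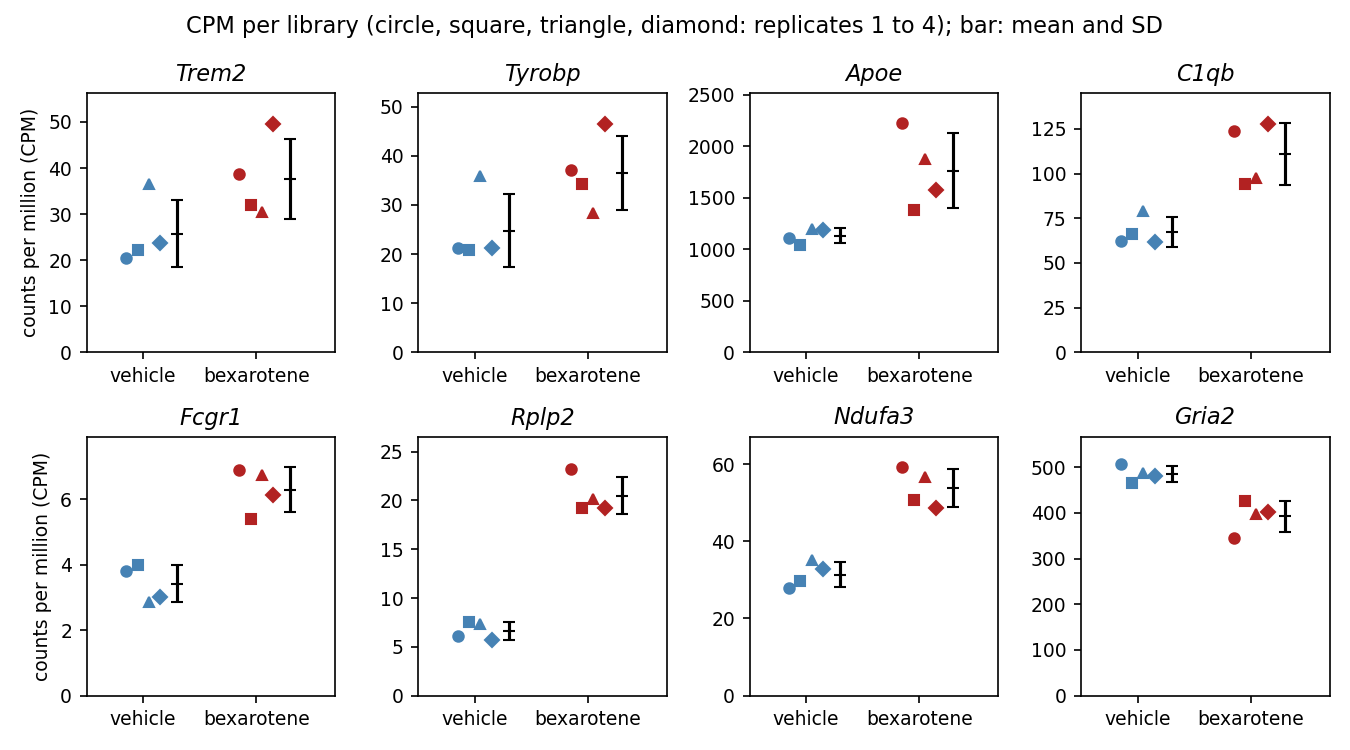
CPM (vertical axes, linear from 0) of 8 named genes in the 4 vehicle and 4 bexarotene libraries, 1 point per library with the symbol giving the replicate number and bars showing mean and SD. Trem2 and Tyrobp overlap between groups through vehicle replicate 3, whereas Apoe, C1qb, Fcgr1, Rplp2 and Ndufa3 are higher and Gria2 is lower in every bexarotene library than in every vehicle library.

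Microglial transcripts were higher under bexarotene as a group. All 14 measured members of the microglia marker list had a positive log2 fold change, with a median of 0.43, and 12 passed when adjusted over the list alone, although 0 passed over all genes. C1qb, a chain of the complement initiator C1q, was at 111 ± 17.4 CPM under bexarotene and 67.3 ± 8.17 CPM under vehicle (SD, n = 4), and C1qc at 91.5 ± 14.2 and 63.4 ± 4.17 CPM. The list rose against other genes in camera with an adjusted p of 1.38e-10, which became adjusted p = 0.412 with an estimated correlation. Its level was higher in each of the 4 bexarotene libraries than in any vehicle library, and the log2 difference was 0.41 within replicates 1 and 3 and 0.49 within replicates 2 and 4.

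Lists of microglial states and functions moved the same way. For phagocytosis, complement and Fc receptors, 31 of 33 members were higher (median log2 fold change 0.35), 7 adjusted over the list alone and 0 over all genes. Fcgr1, an Fc receptor for immunoglobulin G, had a log2 fold change of 0.88 ± 0.17. The list's camera adjusted p was 2.99e-10, and adjusted p = 0.412 with an estimated correlation; its median was 0.22 without bexarotene replicate 4 and 0.53 without vehicle replicate 3. Among homeostatic microglial genes, 16 of 18 were higher (median 0.31), 3 adjusted over the list alone and 0 over all genes, with Tmem119 at 0.43 ± 0.11 and Fcrls at 0.57 ± 0.16. Camera gave 1.93e-05, and adjusted p = 0.432 with an estimated correlation. Genes of plaque-associated microglia, the list that holds Trem2 and Tyrobp, were higher in 24 of 28 (median 0.31), 4 adjusted over the list alone and 0 over all genes, with the lysosomal protease Ctsz at 0.59 ± 0.17. Camera gave 2.64e-05, and adjusted p = 0.432 with an estimated correlation. Within replicates 1 and 3 the log2 difference was 0.37, 0.21 and 0.13 for these 3 lists in turn, and within replicates 2 and 4 it was 0.50, 0.35 and 0.52.

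Interferon-stimulated genes showed the highest median of the 21 gene lists. All 27 members were higher under bexarotene, with a median log2 fold change of 0.93; 13 passed adjusted over the list alone and 0 over all genes. Bst2, which tethers enveloped viruses to the cell surface, was at 7.87 ± 1.91 CPM under bexarotene and 3.41 ± 1.01 CPM under vehicle (SD, n = 4). Ifi27l1 had a log2 fold change of 0.45 ± 0.11. The list rose in camera with an adjusted p of 1.19e-11, and adjusted p = 0.416 with an estimated correlation. Its level relative to the mean of the 8 libraries was 0.94 and 0.86 in bexarotene replicates 1 and 3, but -0.19 and 0.10 in replicates 2 and 4, against -0.60 to -0.31 in the vehicle libraries. The log2 difference was thus 1.40 within replicates 1 and 3 and 0.32 within replicates 2 and 4. The same 2 bexarotene libraries, and vehicle replicate 1, also held the highest levels of striatum markers.

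Antigen presentation genes, which encode major histocompatibility proteins and the machinery that loads them, were higher in 19 of 20 (median 0.58), 8 adjusted over the list alone and 0 over all genes. B2m, the light chain of class I molecules, had a log2 fold change of 0.35 ± 0.10, and H2-D1, a class I heavy chain, 0.40 ± 0.11; every bexarotene library exceeded every vehicle library for both. The list rose in camera with an adjusted p of 9.36e-09, and adjusted p = 0.412 with an estimated correlation. It differed by 0.77 within replicates 1 and 3 and by 0.49 within replicates 2 and 4. Cytokines, chemokines and pattern receptors were higher in 20 of 25 members (median 0.24) and 0 passed adjusted over the list alone or over all genes. Cxcl12 had a log2 fold change of 0.52 ± 0.18 and Cxcl10, an interferon-induced chemokine, 1.76 ± 0.70. Cxcl10 was low throughout, at 3.19 and 2.80 CPM in bexarotene replicates 1 and 3. It was at 0.403 and 0.640 CPM in bexarotene replicates 2 and 4, within the vehicle range of 0.218 to 0.896 CPM. Camera gave an adjusted p of 9.44e-04, and adjusted p = 0.405 with an estimated correlation, and the log2 difference was 0.40 within replicates 1 and 3 and 0.37 within replicates 2 and 4. The median of this list was 0.45 without vehicle replicate 3, 0.20 without vehicle replicate 2 and 0.17 without bexarotene replicate 4.

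**Figure D3:**
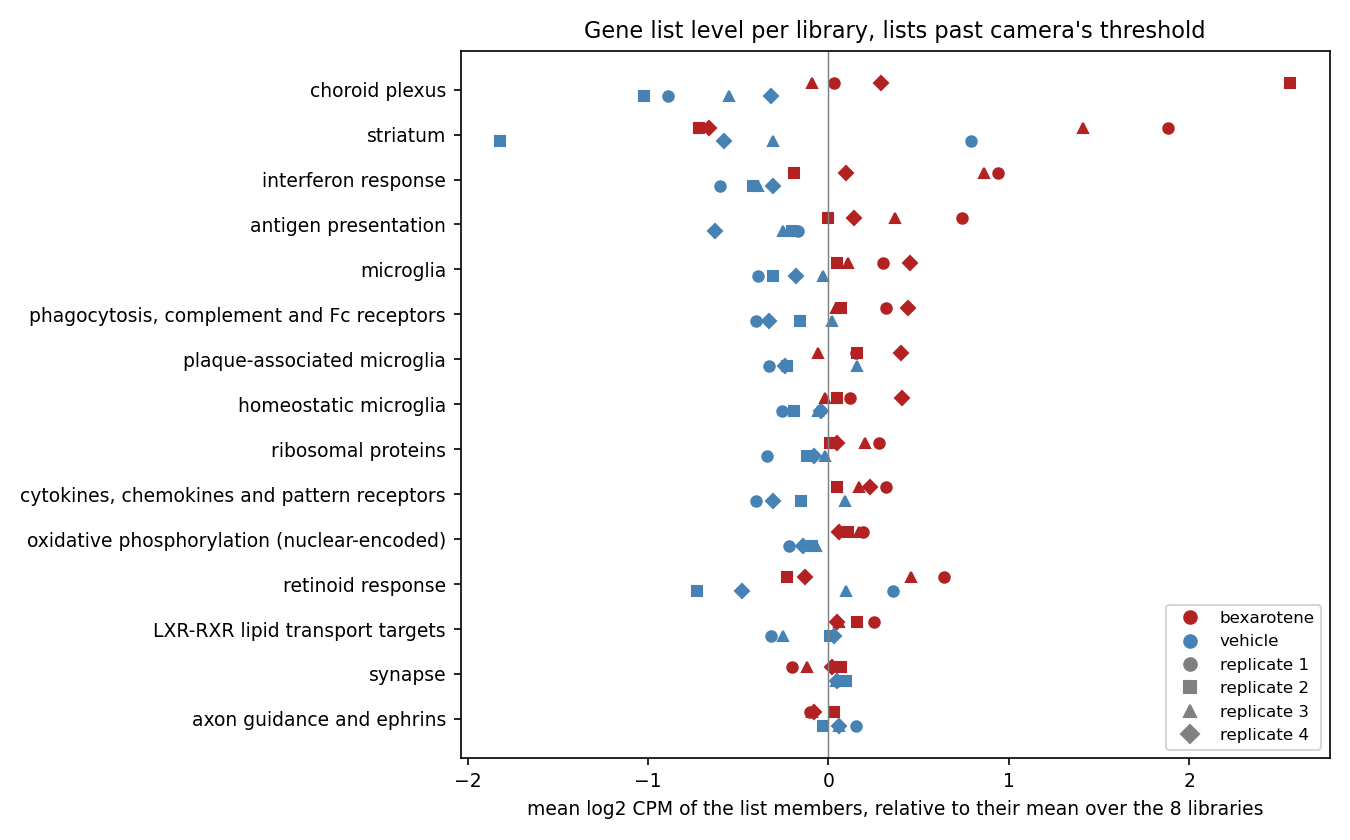
Mean log2 CPM of the members of each list past camera's threshold, relative to their mean over the 8 libraries (horizontal axis), with 1 point per library, colours for groups and symbols for replicate numbers. The bexarotene libraries lie above every vehicle library for microglia, interferon response, antigen presentation and choroid plexus, where bexarotene replicate 2 is highest at 2.56. They also do so for oxidative phosphorylation, ribosomal proteins, phagocytosis, homeostatic microglia and LXR-RXR targets, in part narrowly. For phagocytosis the lowest bexarotene library is at 0.04 and the highest vehicle library at 0.02. In striatum, bexarotene replicates 1 (1.88) and 3 (1.41) are highest and the groups overlap.

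Among the targets of the receptors that pair with the bexarotene receptor, Apoe, the main lipoprotein component of the brain, was higher in every bexarotene library. It averaged 1764 ± 368 CPM under bexarotene and 1132 ± 71.6 CPM under vehicle (SD, n = 4). Its log2 fold change was 0.64 ± 0.14, with an adjusted p of 0.36 over all genes, and it passed when adjusted over its list alone. Abca1, the cholesterol exporter that lipidates Apoe, was at 23.3 ± 6.77 and 25.4 ± 5.03 CPM (SD, n = 4), a log2 fold change of -0.12 ± 0.21, whose sign changed under 4 of the alternatives. The phospholipid transfer protein gene Pltp had a log2 fold change of 0.27 ± 0.09. Of 21 LXR-RXR lipid transport targets, 14 were higher (median 0.12), with Apoe the 1 member past the threshold adjusted over the list alone and 0 over all genes. The list passed camera with an adjusted p of 0.0157, and adjusted p = 0.432 with an estimated correlation; it missed the threshold without vehicle replicate 1 (0.069) or vehicle replicate 3 (0.132). Within replicates 1 and 3 the log2 difference was 0.83 for Apoe and 0.44 for the list, and within replicates 2 and 4 it was 0.41 and 0.09. The largest log2 fold changes in the list were those of Apoc2 (1.44 ± 0.95) and Apoc1 (1.37 ± 0.57). The list's level was -0.32 and -0.25 in vehicle replicates 1 and 3, against 0.01 and 0.03 in vehicle replicates 2 and 4. Liver transcripts, given below, were also lowest in vehicle replicates 1 and 3, and whether they contribute to this list was not tested. The list's median was 0.06 without bexarotene replicate 1.

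Retinoid response genes were higher in 18 of 19 (median 0.21), and 0 passed adjusted over the list alone or over all genes. Stra6, the receptor for retinol-binding protein, had a log2 fold change of 0.50 ± 0.14, and Bco2, a carotenoid-cleaving enzyme, 0.55 ± 0.19. Camera gave an adjusted p of 0.00994, and adjusted p = 0.548 with an estimated correlation; without bexarotene replicate 1, vehicle replicate 2 or vehicle replicate 4 it was 0.0938, 0.0612 and 0.0505. The median was 0.08 without bexarotene replicate 1, 0.34 without replicate 2 and 0.38 without replicate 4 of that group. With the striatum list as a covariate it was 0.667 and the median was -0.0016. The log2 difference was 0.32 within replicates 1 and 3 and 0.43 within replicates 2 and 4. PPAR targets and fatty acid oxidation genes, such as Acadm (0.31 ± 0.10), had a median of 0.07 and a camera adjusted p of 0.0768. It was 0.0363 (median 0.11) without bexarotene replicate 3, 0.0141 (median 0.12) without vehicle replicate 4 and 0.0377 with the Y-linked covariate. Cholesterol synthesis genes, such as Idi1 (-0.67 ± 0.24), had a median of -0.10 and an adjusted p of 0.0768, which was 0.0172 without bexarotene replicate 2, 0.0199 with the length and GC offset, 0.0207 with the offset and the block and 0.0188 with voom. Thyroid hormone response genes, such as Thra (0.15 ± 0.08), had a median of -0.03 and a mean of 0.01, with an adjusted p of 0.945. In these 3 lists 0 members passed over all genes or adjusted over the list alone.

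Genes of the respiratory chain were higher under bexarotene as a group. Of 42 nuclear-encoded oxidative phosphorylation genes, 39 were higher (median log2 fold change 0.23), 18 passed adjusted over the list alone and 0 over all genes, and in 24 every bexarotene library exceeded every vehicle library. Ndufa3 was at 53.8 ± 5.04 CPM under bexarotene and 31.4 ± 3.17 CPM under vehicle (SD, n = 4), and Ndufs6, another complex I subunit, at 24.5 ± 1.90 and 15.9 ± 1.58 CPM. The list rose in camera with an adjusted p of 5.12e-18, and adjusted p = 0.405 with an estimated correlation; it was the 1 list that passed fry, with an adjusted p of 0.0377. Ribosomal protein genes were higher in 36 of 43 (median 0.27), 13 adjusted over the list alone, and 1, Rplp2, over all genes. Camera gave an adjusted p of 2.99e-10, and adjusted p = 0.432 with an estimated correlation; the median was 0.17 without vehicle replicate 1. Within replicates 1 and 3 the log2 difference was 0.33 for the first list and 0.42 for the second, and within replicates 2 and 4 it was 0.19 and 0.13. The median length of the transcripts was 850 nt for the first list and 833 nt for the second.

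Fold changes followed transcript length across the whole transcriptome. Over 11453 genes with a mean above 2 log2 CPM, the log2 fold change correlated with transcript length at a Spearman rho of -0.47 and with GC content at 0.37; these are correlations across genes, which are not independent replicates. The median log2 fold change was 0.25 for transcripts under 700 nt and -0.13 for those over 6000 nt. The trend was strongest in bexarotene replicates 1 and 3. Their levels relative to the mean over the 8 libraries correlated with length at -0.42 and -0.43. The same correlation was 0.03 in both other bexarotene libraries and 0.07 to 0.31 in the vehicle libraries. On this relative scale a decline in some libraries forces a rise in others. The vehicle values therefore do not by themselves show a length trend in those libraries. With the length and GC offset, the median of the oxidative phosphorylation list was 0.07 and that of the ribosomal list 0.06.

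**Figure D4:**
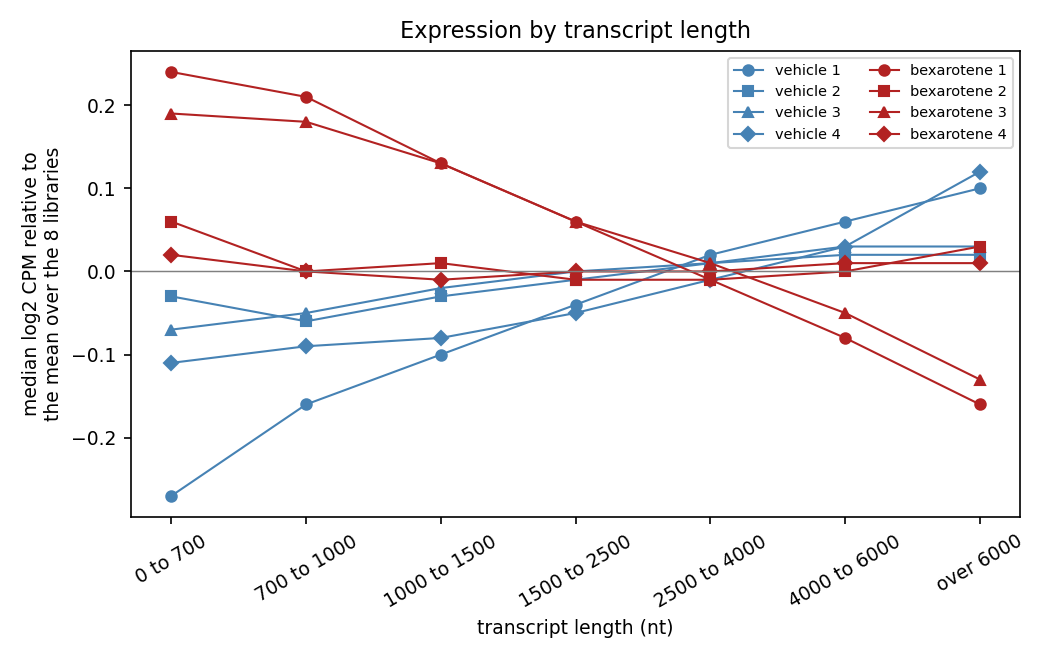
Median log2 CPM relative to the mean over the 8 libraries (vertical axis) for genes in 7 classes of transcript length (horizontal axis, nt), with 1 line per library. Bexarotene replicates 1 and 3 decline from 0.24 and 0.19 in the shortest class to -0.16 and -0.13 in the longest. Relative to the common mean, the vehicle libraries run the other way, which the centring in part forces.

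Synaptic and axon guidance genes, which have long transcripts, were lower. Of 34 synapse genes, 28 were lower (median log2 fold change -0.15), and 0 passed adjusted over the list alone or over all genes. Gria2, a subunit of AMPA-type glutamate receptors, was at 392 ± 34.4 CPM under bexarotene and 485 ± 17.0 CPM under vehicle (SD, n = 4), and the neurotrophin gene Bdnf had a log2 fold change of -0.23 ± 0.10. The list fell in camera with an adjusted p of 3.06e-04, and adjusted p = 0.432 with an estimated correlation. Of 36 axon guidance and ephrin genes, 31 were lower (median -0.15) and 0 passed adjusted over the list alone or over all genes, with Slit3 at -0.23 ± 0.10 and Robo2 at -0.29 ± 0.13. Camera gave an adjusted p of 0.0113, and adjusted p = 0.412 with an estimated correlation; it was 0.0867 without vehicle replicate 1. Within replicates 1 and 3 the log2 difference was -0.21 for synapse and -0.20 for axon guidance, and within replicates 2 and 4 it was -0.03 and -0.04. The synapse median was -0.07 without bexarotene replicate 1. Both lists missed the threshold with the length and GC offset, at 0.0582 for synapse (median -0.07) and 0.161 for axon guidance (median -0.06). With the offset and the replicate block, synapse passed at 0.048 (median -0.07) and axon guidance did not, at 0.123 (median -0.02). With the offset alone Gria2 had a log2 fold change of 0.03.

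App, Prnp and the lists on amyloid and Alzheimer risk gave little difference between the group means. App had a log2 fold change of -0.01 ± 0.12 and Prnp -0.04 ± 0.11. For both genes the clusters of libraries differed in opposite directions, with 2 libraries per group in each cluster. In the cluster whose vehicle libraries were rich in Xist, the log2 difference was -0.32 for App and -0.28 for Prnp. In the other cluster it was 0.30 and 0.20. The signs of the App and Prnp fold changes also changed under some scalings or left-out libraries, so no direction is given. Genes of amyloid precursor processing and clearance, such as Lrp8 (-0.28 ± 0.09), had a median of 0.02 and an adjusted p of 0.967. Late-onset Alzheimer risk genes had a median of 0.04, which was -0.09 with voom, and an adjusted p of 0.516; 1 of the 23, Apoe, passed adjusted over the list alone.

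Neurogenesis genes, such as Dcx (-0.36 ± 0.15), had a median log2 fold change of -0.01 and a camera adjusted p of 0.703. Immediate early genes, such as Gadd45b (0.40 ± 0.14), had a median of 0.10 and an adjusted p of 0.631; with the Y-linked covariate these were 0.23 and 0.0118, and with the striatum covariate 0.34 and 0.0189. Glucocorticoid response genes, such as Mt1 (0.34 ± 0.11), had a median of -0.15 but a mean of 0.00, with an adjusted p of 0.516 that was 0.037 (median -0.24) without bexarotene replicate 4 and 0.0183 with the length and GC offset and the block. Heat shock and unfolded protein genes, such as Ddit3 (0.31 ± 0.12), had a median of 0.11 and an adjusted p of 0.108, which was 4.96e-04 (median 0.19) without vehicle replicate 1 and 0.0411 with voom. In the lists of this paragraph 0 members passed over all genes or adjusted over the list alone.

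Markers of neurons, astrocytes and the oligodendrocyte lineage did not pass. The median log2 fold change was -0.0032 for neurons (Mtap2 -0.22 ± 0.15; camera adjusted p = 0.614), 0.05 for astrocytes (S100b 0.33 ± 0.11; 0.497), 0.06 for oligodendrocytes (Mog 0.39 ± 0.26; 0.36) and 0.02 for their precursors (Cacng4 0.20 ± 0.28; 0.967). The oligodendrocyte list passed without bexarotene replicate 3 (0.0392, median 0.21) and without vehicle replicate 4 (0.00189, median 0.32), so its median depends on single libraries. It also passed with the Y-linked (0.00139, median 0.29) and striatum (0.0069, median 0.34) covariates. The neuron median was -0.09 without vehicle replicate 1. Vascular markers were near the threshold: endothelial genes had a median of 0.17 (Vwf 0.86 ± 0.31; 0.054) and pericyte and smooth muscle genes 0.26 (Kcnj8 0.51 ± 0.22; 0.0768). The endothelial list passed without bexarotene replicate 2 (0.015) or 3 (0.0213) and without vehicle replicate 2 (0.00779) or 4 (0.016, median 0.26). With all libraries it passed with DESeq2 (0.0168), the exact test (0.0113), voom (0.0112), the stricter filter (0.0353), the length and GC offset (0.0329), the offset with the block (0.048) and the Y-linked (0.00957) and striatum (0.0456) covariates. The pericyte list passed without bexarotene replicate 2 (0.0316) and without vehicle replicate 2 (0.0336). With all libraries it passed with DESeq2 (0.0393), the exact test (0.0338), voom (0.0211), the offset (0.0233), the offset with the block (0.0207) and the Y-linked covariate (0.0251). Neither passed camera with an estimated correlation or fry. Endothelial and pericyte genes differed by 0.50 and 0.64 (log2) within replicates 1 and 3, but by -0.07 and -0.08 within replicates 2 and 4. Perivascular macrophage and monocyte genes had a median of 0.21 (Cd163 0.59 ± 0.35; 0.284), and without vehicle replicate 1 their adjusted p was 0.00266 and their median 0.53.

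Markers of tissue next to the cortex varied widely between libraries. All 12 choroid plexus genes were higher (median log2 fold change 1.46), 2 adjusted over the list alone and 0 over all genes. Ttr, the transthyretin carrier made by this epithelium, was at 68.0, 1397, 58.7 and 213 CPM in bexarotene replicates 1 to 4 and at 6.14 to 33.0 CPM in the vehicle libraries, and Clic6 had a log2 fold change of 1.49 ± 0.41. The list rose in camera with an adjusted p of 8.70e-05, and adjusted p = 0.432 with an estimated correlation; without bexarotene replicate 2 it was 0.0106 and the median 0.46. The log2 difference was 0.69 within replicates 1 and 3 and 2.10 within replicates 2 and 4. All 12 striatum genes were also higher (median 1.04), with 0 past the threshold adjusted over the list alone or over all genes, but their level was raised in bexarotene replicates 1 and 3 and vehicle replicate 1 and low elsewhere. Ppp1r1b, a signalling protein of striatal projection neurons, was at 329 and 236 CPM in those 2 bexarotene libraries and at 159 CPM in that vehicle library, against 74.2 to 89.4 CPM in the other 5. Rgs9 had a log2 fold change of 1.22 ± 0.71. Camera gave the list an adjusted p of 0.0157, and adjusted p = 0.796 with an estimated correlation; without bexarotene replicate 1 or 3, or vehicle replicate 2 or 4, it was 0.251, 0.128, 0.333 and 0.0507. The median was 0.47 without bexarotene replicate 1. The log2 difference was 1.40 within replicates 1 and 3 and 0.51 within replicates 2 and 4.

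The other marker lists did not pass camera. The median log2 fold change was 0.16 for meninges and fibroblasts (Col3a1 0.66 ± 0.65; adjusted p = 0.188), where the replicate block gave an adjusted p of 0.0208 with a median of 0.27 and the fit without vehicle replicate 1 gave 6.21e-05 with a median of 0.58. It was 0.55 for blood (Fech -0.13 ± 0.07; 0.967), 0.14 for ependymal cells (1110017D15Rik 0.88 ± 0.49; 0.879) and 0.05 for thalamus and habenula (Tac2 -0.33 ± 0.15; 0.676), where camera's direction was down. Hippocampus had a median of -0.07 and a mean of 0.10 (Homer3 0.39 ± 0.13; 0.516). Neutrophil markers had a median of -0.11 and a mean of 0.05 (Lcn2 1.60 ± 0.70; 0.631). The sex-linked list had a median of -0.54 (0.188) while camera's direction was up. Of all these lists, 0 members passed adjusted over the list alone or over all genes.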

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

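Each sample was compared with the 3 others of its group for the named genes and lists. In 6 of 188 groups of 4, 1 library stood apart by Dixon's test; chance gives about 5%. All explanations weighed in this part were tested only after the results had been seen.

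Tyrobp was at 35.9 CPM in vehicle replicate 3, and at 20.8 to 21.2 CPM in the other 3 vehicle libraries. S100b was at 75.4 CPM in vehicle replicate 2, and at 90.6 to 93.7 CPM in the others. The list of PPAR targets was at 0.02 in bexarotene replicate 3, relative to the mean of all libraries, and at 0.09 to 0.10 in the others of that group. Neurogenesis genes were at 0.20 in vehicle replicate 4, and at -0.09 to -0.05 in the others. Hippocampus markers were at 0.45 in bexarotene replicate 2, and at -0.09 to -0.01 in the others.

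Choroid plexus markers were at 2.56 in bexarotene replicate 2, and at -0.09 to 0.29 in the other bexarotene libraries. No explanation was tested for this.

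A further pattern stands out without any single library being far from its group: all 4 bexarotene libraries hold both Xist and Y-linked transcripts, while each vehicle library holds 1 kind almost alone. Males that express Xist are argued against, since the highest Y-linked share was 64.3% of the mean of the 2 male-like vehicle libraries, of which the lower had 97.4%. Reads of bexarotene replicate 2 in replicates 1 and 3 are argued against too, because Ttr there reached at most 25.2% of the level needed, but in replicate 4 it reached 138%, so this stays open there. A mixture of tissue, RNA or reads of both sexes may explain the pattern, but the Y-linked and Xist shares add up to 77.4%, 94.8%, 82.2% and 85.7% in bexarotene replicates 1 to 4 against 89.4% to 111% in the vehicle libraries, and with 2 vehicle libraries of each kind this cannot decide it. Bexarotene libraries of 1 sex alone, like those of vehicle, are argued against. Every bexarotene library had a Y-linked share of at least 7.13% and an Xist share of at least 30.5%. In every vehicle library the lesser share was at most 0.310%. Pooled animals and carry-over from other samples stay open, and the labels do not give the sex of the animals. All tests here treat the libraries as independent, with the same spread in both groups. Carry-over would break the first assumption, and pooling in the bexarotene group alone the second. The p-values, SDs and counts of genes without overlap are to be read with this limit.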

How the results depend on the processing

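The tests with the length and GC offset, the covariates, the cluster term, the offset with the replicate block and 1 row per gene were chosen after the data had been seen; the others were set before the data were examined. Of 113 results, all kept their direction and side of the threshold with RLE factors, without a low-count filter, with counts summed per symbol and with 1 row per gene. Rplp2 passed in every setting, with a log2 fold change of 1.43 to 1.69. Trem2 ranged from 0.37 to 0.77 and passed in none, with adjusted p from 0.269 to 1. The stricter filter gave a value for 108 results, since it removed some genes of low count. Log2 fold changes of named genes short of the threshold in the quasi-likelihood test varied as well, for example Mt1 from 0.07 to 0.43, Ddit3 from 0.10 to 0.40, Ndufs6 from 0.35 to 0.69, Cxcl10 from 0.56 to 2.17 and Robo2 from -0.43 to -0.07 over the settings. For the changes below the cause was not tested unless stated.

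DESeq2 called 104 genes (78 up, 26 down) and the exact test 37 (34 up, 3 down). An adjusted p below 0.1 gave 3 genes, all 3 up, by construction. The Y-linked covariate gave 2 genes, both of these 2 up, and the cluster term 3 genes, 3 up. Leaving out 1 library gave 1 to 2 genes, 1 to 2 of them up and 0 down.

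The number of lists past camera's threshold was 0 with an estimated correlation and 1 with fry, and lay between 13 and 20 in the other settings. With an estimated correlation the adjusted p was 0.405 for cytokines and oxidative phosphorylation; 0.412 for phagocytosis, antigen presentation, axon guidance and microglia; 0.416 for interferon response; 0.432 for LXR-RXR targets, homeostatic and plaque-associated microglia, synapse, ribosomal proteins and choroid plexus; 0.548 for retinoid response and 0.796 for striatum. Fry gave 0.0734 for cytokines, 0.0969 for antigen presentation and microglia, 0.149 for phagocytosis, interferon response and ribosomal proteins, 0.16 for LXR-RXR targets and plaque-associated microglia, 0.193 for homeostatic microglia, 0.248 for choroid plexus, 0.267 for axon guidance, 0.28 for synapse, 0.302 for retinoid response and 0.541 for striatum.

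With the length and GC offset, axon guidance (adjusted p = 0.161) and synapse (0.0582) missed the threshold, and the log2 fold change became positive for Abca1 (0.03), App (0.14), Gria2 (0.03) and Fech (0.01). With the replicate block as well, axon guidance and ribosomal proteins were both at 0.123, and Abca1 (0.02), App (0.15), Gria2 (0.03), Fech (0.0038) and Uty (0.75) became positive. The block alone made Uty positive (0.56), added the meninges list and changed no other call. App was positive with upper quartile factors (0.02) and with library size only (0.01), and Uty with voom (3.15), the Y-linked covariate (2.83) and the cluster term (0.79). Uty is itself part of the Y-linked covariate. The Y-linked covariate also took striatum to 0.0832.

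The striatum covariate removed the striatum list itself by construction (adjusted p = 0.452, median -0.10). With it, retinoid response was at 0.667 with a median of -0.0016 and synapse at 0.0791, Abca1 (0.02), App (0.0045) and Uty (0.45) became positive, and Cacng4 (-0.17) and Col3a1 (-0.08) negative.

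Without 1 library at a time, Abca1 lay between -0.28 and 0.03, App between -0.08 and 0.05, Prnp between -0.10 and 0.04 and Cacng4 between -0.02 and 0.39. The adjusted p lay between 0.00321 and 0.132 for LXR-RXR targets, 0.00105 and 0.0867 for axon guidance, 7.38e-04 and 0.0938 for retinoid response, and 4.84e-04 and 0.333 for striatum.

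Other lists passed only under some settings. The offset added cholesterol synthesis (0.0199), endothelial cells (0.0329) and pericytes (0.0233). The offset with the block added these 3 (0.0207, 0.048 and 0.0207), glucocorticoid response (0.0183), oligodendrocytes (0.048) and meninges (0.012), and synapse passed there (0.048). The Y-linked covariate added PPAR targets (0.0377), immediate early genes (0.0118), oligodendrocytes (0.00139), endothelial cells (0.00957), pericytes (0.0251) and the sex-linked list (3.01e-09). The sex-linked list holds the Y-linked genes from which this covariate was made, so no conclusion is drawn from its passing. The striatum covariate added immediate early genes (0.0189), oligodendrocytes (0.0069) and endothelial cells (0.0456). Voom added cholesterol synthesis (0.0188), endothelial cells (0.0112), heat shock (0.0411), meninges (0.0211) and pericytes (0.0211). DESeq2 and the exact test added endothelial cells (0.0168 and 0.0113) and pericytes (0.0393 and 0.0338), and the stricter filter endothelial cells (0.0353).

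With voom the medians of the Alzheimer risk, neutrophil and sex-linked lists, none past the threshold, moved from 0.04 to -0.09, from -0.11 to 1.19 and from -0.54 to 3.29. The thyroid median moved from -0.03 to 0.12 with the Y-linked and to 0.11 with the striatum covariate.

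The low-count filter left 16069 of 22869 symbols to test; how far depth limits the others was not tested.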

Other observations

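All tests in this part were chosen after the results had been seen. The values of the next paragraph belong to no comparison, and their genes were chosen after their values were seen.

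Genes of liver, such as the plasma protein albumin, were found at low levels: the sum of 14 of them was 62.3, 176, 50.1 and 58.7 CPM in bexarotene replicates 1 to 4 and 1.505, 138, 8.10 and 174 CPM in vehicle replicates 1 to 4. Alb alone was at 22.6 to 69.4 CPM in the bexarotene libraries and at 0.0705, 53.0, 2.98 and 82.4 CPM in the vehicle libraries. The hypothalamic peptide gene Avp was at 48.5 and 25.5 CPM in bexarotene replicates 1 and 3 and at 68.5 CPM in vehicle replicate 1, against 0.654 to 1.83 CPM elsewhere. Oxt was at 6.02, 3.27 and 8.14 CPM in these 3 libraries and Trh at 24.1, 29.7 and 28.0 CPM.

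Oxidative phosphorylation and ribosomal protein genes were higher under bexarotene, and both have short transcripts. With the trend of transcript length and GC content removed per library, the median log2 fold change went from 0.23 to 0.07 for the first list and from 0.27 to 0.06 for the second. A difference in RNA or library quality that follows transcript length may therefore account for most of both shifts. Both stayed past camera's threshold with the offset, at an adjusted p of 5.39e-04 and 0.0325. The ribosomal list lost its call with the offset and the block together (0.123), neither list passed at an estimated correlation without the offset (0.405 and 0.432), and a response to bexarotene stays open.

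Microglia, interferon and antigen presentation genes were, as lists, higher in every bexarotene library than in any vehicle library. The length and GC offset left their medians at 0.38, 0.91 and 0.52, and the striatum covariate at 0.44, 0.53 and 0.43, with all 3 lists past camera's threshold in both but none at an estimated correlation without them (0.412, 0.416 and 0.412). The upper 95% bound of the part that goes with the length and GC trend was 0.09, 0.06 and 0.17, below 0.5 of each group difference (0.23, 0.43 and 0.31), which argues against that trend as the source of most of the shifts. For the striatum level the bound was 0.14 for microglia, which argues against it there, but 0.48 for interferon and 0.33 for antigen presentation, so with 8 libraries it cannot be told apart from a group difference for these 2 lists. Choroid plexus markers separated the groups as fully (-0.09 to 2.56 against -1.02 to -0.32). So did the oxidative phosphorylation, ribosomal protein, phagocytosis, homeostatic microglia and LXR-RXR lists, so full separation is not particular to these lists. For microglia, interferon and antigen presentation in turn, vehicle replicate 1 was at -0.39, -0.60 and -0.17. Vehicle replicate 3, also rich in Xist, was at -0.03, -0.39 and -0.25. The Y-linked-rich vehicle replicates were at -0.31, -0.42 and -0.20 (replicate 2) and -0.18, -0.31 and -0.63 (replicate 4). Every bexarotene library lay above both kinds, which argues against sex as the only source of these 3 shifts. Admixed tissue, the sex of the animals and a response to bexarotene may each contribute to them.

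The 8 libraries can be split into 4 and 4 in 35 ways. For the number of genes, 3 of the 35 splits gave at least the 1 gene of the real split, so chance could not be excluded. The highest other value, 1136 genes, came from replicates 1 and 3 against 2 and 4 and points to a structure of the samples. For the lists, 10 of the 35 splits gave at least the real 15, with 21 as the highest of the others, so chance could not be excluded either. Of the 8 splits that part all 4 same-numbered pairs, 3 gave at least 15 lists, with 19 as the highest of the others, and 1, the real one, gave a gene.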
